A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

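Ribosome footprints, the stretches of mRNA that a ribosome shields from nuclease, were sequenced from 8 libraries of Saccharomyces cerevisiae. The libraries came from wild type and from a zuo1 mutant, 2 genotypes that were both pdr5 deletion strains per the protocol, with 2 libraries in each of 4 groups. Cells were treated for 45 min with 100 uM of the proteasome inhibitor MG132, alone or with 2 mg/mL of the proline analogue azetidine-2-carboxylic acid (AZC). Per the labels, the authors used FastQC, cutadapt 4.9, Bowtie2 2.4.4, HISAT2 2.2.1 and SAMtools 1.21 on genome build R64. The role of each tool, the annotation, the read lengths kept and any removal of duplicates are not given in the sources used here. The deposited table has other units than counts: the authors gave 1 record per footprint, with its library, gene, P-site codon number, the codons in the E, P and A sites and the position of the P-site nucleotide within its codon. The P-site nucleotide lay 13 or 14 nt from the 5' end of the read in the records. All 24623043 records were used.

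Footprints were tallied per gene and library with R 4.3.3 and the package data.table, version 1.17.8. The libraries held 1986105 to 4809398 footprints, which sets the precision of each value. Intervals of shares are 95% Wilson intervals and cover counting error only, since footprints without molecular identifiers are not independent molecules. Of the 6182 genes in the table, 5746 matched a symbol by locus tag in a RefSeq annotation of R64, from which the coordinates were taken, and 436 did not. A gene was tested when 2 libraries held at least the CPM that equal 10 footprints in the library of median depth, with 15 footprints or more in total, which left 5325 genes. Libraries were scaled by the trimmed mean of M values, with trims of 30% and 5%, computed by own code. The count models planned in the design, edgeR with DESeq2 as its alternative, were not used. They were kept for tables deposited as counts, which this is not, although the tallies are whole numbers to which they could be fitted. Instead limma 3.58.1 with voom weights and a prior count of 0.5 was fitted to the tallies with 4 group means. The 5 planned contrasts were AZC in wild type, AZC in zuo1, the difference of these (the interaction), zuo1 in MG132 and zuo1 in MG132 plus AZC. The zuo1 effect averaged over both treatments was added after the data were seen. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested.

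Gene lists were fixed before the data were examined and were tested with camera at a preset correlation of 0.01, with at least 5 members tested. The call was checked with a correlation estimated from the data and with fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes. Members were counted by the test over all genes and as adjusted over the list alone. The genes named were fixed by a rule written before the data were examined: ZUO1, SSZ1, SSB1, SSB2 and PDR5 always, up to 8 called genes with the largest log2 change in each direction, with a mean of at least 50 footprints and groups that did not overlap (this last condition not for the interaction), 4 members of each called list and up to 2 called members of the others. Genes named outside the rule are marked where they appear.

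Codon occupancy was the footprint count on a codon relative to the mean of its gene, over 2347 genes with at least 100 footprints in every library, leaving out the first 15 and the last 5 codons. It was computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 for 61 sense codons in the E, P and A sites and for 20 amino acids (60 features). The table shows the codon at 84.01% of the codon positions, those that lay in the E, P or A site of some footprint. Density along coding sequences was computed in 12 bins over 1329 genes of at least 400 codons, and density around proline codons in 13 bins of 10 codons from -30 to 99. These log2 values were compared with limma on the same 4 groups, with the adjustment within each kind of feature. Polarity, shares of footprints at start and stop, and slopes of a library's counts on gene properties were single values per library. They were compared with exact two-sided permutation tests (scipy 1.17.1), 18 tests adjusted together. The smallest p these allow is 0.0286 for 4 libraries against 4 and 0.33 for 2 against 2. The slope on proline content used 4489 genes with at least 80% of their codons known, and the slopes on coding length and mean expression all 5325 genes tested. Figures were drawn with matplotlib 3.10.9.

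The procedures were tested on simulated data. In counts drawn with 1 median spread for all genes, taken from all 4 groups, 47.8% of genes changed 1.5-fold, 85.1% of genes changed 2-fold and 100% of genes changed 4-fold were called in the contrast of AZC in wild type, as were 6 of 5095 unchanged genes. A changed gene list was called and 0 of 20 unchanged lists were called. Genes were drawn independently of each other there, and the unchanged lists were random. How often lists whose genes move together are falsely called is therefore not shown by it. Positions were simulated with counting error only and no spread between replicates. There a proline occupancy change of 0.485 at the A site was returned as 0.44 and a density change of 0.379 at codons 2 to 15 as 0.382. How often such changes are called, or falsely called, at the spread of these libraries is not shown by it. Of the 60 amino acid features in that simulation, 24 besides proline at the A site were called although no change was put into them, by at most 0.049, so a call of a small occupancy change is weak evidence. Beside the density change, 0 of the other position bins were called. Alternatives were median-of-ratios scaling, no filter on low counts, interior codons only, the groups compared alone, each library left out in turn, the replicate number as a block, within each genotype for the effects of AZC (with it, AZC in wild type gave 104 genes), other minimum counts, equal gene weights, capped positions and longer stretches left out at the 5' end. Added after the data were seen were limma-trend, a fit without the zuo1 libraries numbered 2, a block with crossed numbers in zuo1 and a count without the open reading frame YLR154C-G. For features other than genes, the fits of the groups compared alone were added then too. The block rests on the protocol, in which 2 aliquots of a culture were treated with and without AZC. The labels do not say that libraries of the same number shared a culture. Their deviations from the group means correlated at 0.17 in wild type and -0.53 in zuo1. No library was left out of the values reported first.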

Results

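Ribosome footprints were counted on 6182 genes of budding yeast in 8 libraries, 2 from each of 4 groups: wild type with MG132, wild type with MG132 plus AZC, zuo1 with MG132 and zuo1 with MG132 plus AZC. MG132 inhibits the proteasome. AZC is an analogue of proline that is built into proteins in its place and hinders their folding. Zuo1 is a J-domain protein that sits on the ribosome with Ssz1 and there stimulates Ssb, the Hsp70 chaperone of nascent chains. The wild-type libraries held 4420591 and 3401753 footprints with MG132, and 1986105 and 2307897 with MG132 plus AZC. The zuo1 libraries held 4809398 and 2113141 with MG132, and 3011511 and 2572647 with MG132 plus AZC. Levels below are scaled footprint counts (CPM, mean ± SD, n = 2), and changes are on the log2 scale, given ± SE. No mRNA sequencing libraries are among the samples, so a change in footprints cannot be split into mRNA level and translation.

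ZUO1 (YGR285C, chromosome VII, 1061852 to 1063153, build R64) had 779, 739, 502 and 495 CPM before scaling in the 4 wild-type libraries, against 3.74, 18.9, 4.98 and 6.61 in the 4 zuo1 libraries. PDR5, the drug exporter deleted in both strains, had between 0 and 2 footprints in each of the 8 libraries. Replicates of wild type correlated across 5325 genes at r = 0.991 with MG132 and 0.985 with MG132 plus AZC, where genes are not independent replicates. Replicates of zuo1 correlated at 0.958 and 0.976. The library labelled zuo1 MG132 replicate 2 correlated at 0.986 with the library labelled zuo1 MG132 plus AZC replicate 1, and the libraries labelled zuo1 MG132 replicate 1 and zuo1 MG132 plus AZC replicate 2 correlated at 0.979. The median absolute log2 difference between replicates was 0.143 and 0.17 in the wild-type groups and 0.327 and 0.203 in the zuo1 groups. All values below keep the groups as labelled, and values without the zuo1 libraries numbered 2, a setting chosen after the data were seen, are given beside some of them.

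The first comparison asked what AZC changed in wild-type cells under proteasome inhibition. Most ribosomal protein genes fell, and 3 of 30 genes of the general stress response rose. Of 138 cytosolic ribosomal protein genes, 132 fell and 0 rose, with a median log2 change of -1.68. RPS9B (YBR189W, chromosome II, 604508 to 605508), a protein of the small subunit, went from 1447 ± 9.76 to 274 ± 23.4 CPM, a log2 change of -2.40 ± 0.16 (adjusted p = 0.001). SSB1 (YDL229W), the ribosome-bound Hsp70, went from 1208 ± 45.9 to 218 ± 39.6 (log2 -2.48 ± 0.27, adjusted p = 0.0016), and its paralogue SSB2 (YNL209W) fell by 1.99. SSZ1 (YHR064C), the partner of Zuo1, fell by 1.10 (adjusted p = 0.014), and ZUO1 itself had a log2 change of -0.92 ± 0.27 (adjusted p = 0.06). HSP12 (YFL014W), a small stress protein of membranes, rose from 890.3 ± 46.9 to 5289 ± 9.07 (log2 2.57 ± 0.58, adjusted p = 0.027), and GPH1 (YPR160W), glycogen phosphorylase, rose from 219.5 ± 31.7 to 897 ± 58.5 (log2 2.04 ± 0.48, adjusted p = 0.032).

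The genes that rose most in wild type with AZC besides HSP12 and GPH1 were EGO4 (log2 2.84), FUN19 (2.44), FMP16 (2.36), RIE1 (1.98), SYM1 (1.96) and IGD1 (1.80), the last an inhibitor of glycogen breakdown. Besides RPS9B and SSB1, those that fell most were HPT1, which salvages purine bases (-2.83), NSR1, a nucleolar protein of rRNA processing (-2.60), ILV5, an enzyme of branched-chain amino acid synthesis (-2.52), RPS22A (-2.48), RPL21B (-2.47) and RPA49, a subunit of RNA polymerase I (-2.34). In all, limma called 92 genes as risen and 561 as fallen of 5325, and 1729 genes had an unadjusted p under 0.05. With only the wild-type libraries in the fit, which leaves out the wider zuo1 spread, 1024 rose and 1191 fell of 5231. In that fit HSP26, a small heat shock chaperone, rose from 169 ± 19.5 to 1888 ± 85.7 (log2 3.55 ± 0.11, adjusted p = 7.8e-11), while over all 8 libraries its change was 3.49 ± 1.17 (adjusted p = 0.084). SSA4, an inducible cytosolic Hsp70, and PUT1, proline oxidase, chosen after their values were seen, rose in that fit by 2.01 ± 0.11 (adjusted p = 7.5e-09) and 2.38 ± 0.21 (adjusted p = 5.1e-07), with adjusted p = 0.29 and 0.11 over all 8 libraries. The count was 93 and 81 without the first or second wild-type MG132 library, 146 and 106 without the first or second wild-type AZC library, 1733 and 1662 without the first or second zuo1 MG132 library, and 104 with the replicate number as a block.

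Of the 23 gene lists tested, 10 were called by camera at the preset correlation and none with an estimated correlation. The adjusted p with an estimated correlation was 0.5 for the ribosomal proteins, the ribosome-associated chaperones and glycolysis and 0.61 for elongation factors, initiation factors, Gcn4-type genes and the chaperonin. It was 0.69 for ribosome biogenesis and general stress, and 0.74 for the heat shock chaperones. At the preset correlation it ran from 1.3e-61 for the ribosomal proteins to 0.0097 for the heat shock chaperones. Among 65 ribosome biogenesis genes, 18 fell and 0 rose (44 fell when adjusted over the list alone, median -1.64), among them NOP58 (-2.21), NOP1 (-1.74) and NOP56 (-1.80), core proteins of the particles that methylate rRNA. Of 17 elongation and termination factors, 14 fell (17 adjusted over the list alone, median -0.97), with YEF3, elongation factor 3, at -2.08, TEF1, elongation factor 1A, at -2.06 and EFB1 at -1.45. Of 26 initiation factors, 14 fell (22 adjusted over the list alone, median -0.67), with TIF1 at -1.17 and the poly(A)-binding protein PAB1 at -1.09. For the ribosomal proteins, 134 fell when adjusted over the list alone. Of 24 genes of glycolysis and fermentation, 16 fell (20 fell and 1 rose adjusted over the list alone, median -0.81), including PDC1, pyruvate decarboxylase (-1.58), PGI1 (-1.35), ENO2 (-1.02) and PGK1 (-0.90). Of 45 Gcn4-type biosynthesis genes, 16 fell (30 adjusted over the list alone, median -0.55), including LYS9 (-1.26), HOM3 (-1.05) and ARO2 (-0.92). Of 9 ribosome-associated chaperones, 5 fell (7 adjusted over the list alone, median -0.93), EGD1 at -0.94 among them. Of 15 chaperonin and prefoldin genes, 6 fell (10 adjusted over the list alone, median -0.45), CCT7 at -1.03 and CCT4 at -0.80 among them. Of 30 general stress genes, 3 rose and 1 fell (11 and 1 adjusted over the list alone, median 1.27), with HOR7 at 1.27 and the fallen YGP1 at -0.79. Of 27 cytosolic heat shock chaperones, 0 rose by limma over all 8 libraries and CPR3, a mitochondrial cyclophilin that the list holds, fell (-0.63), the same counts as adjusted over the list alone, with a list median of 0.64.

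By fry, the ribosomal proteins of wild type with AZC moved down on balance (adjusted p = 0.009). Among 33 proteasome subunits 0 rose and 0 fell (median -0.14), also when adjusted over the list alone. PDR10, a transporter of the drug resistance list, rose (1.34), as did TMC1 of the 20 ubiquitin and degradation factors (0.77) and PRM5 of the 21 cell wall genes (0.97). Of 33 genes of ribosome rescue and mRNA surveillance, 2 fell, ASC1, a protein of the small subunit, at -2.11 and NEW1 at -0.82. Of 21 genes of proline and arginine metabolism, 3 fell, PRO3, the last enzyme of proline synthesis, at -0.84 and the methionine transporter MUP1 at -0.93 among them. FET3 (-0.89) and FTR1 (-1.12) of 22 iron genes, RNR1 (-1.15) and POL30 (-1.01) of 21 histone and cell cycle genes, GPX2 (-0.68) and ZWF1 (-0.51) of 22 oxidative stress genes, ATP3 (-0.58) of 35 oxidative phosphorylation genes, and PDI1 (-0.57) and FPR2 (-0.72) of 22 genes of the unfolded protein response fell as well, none of these lists being called. None of 9 mitochondrial chaperones or 6 mating type a genes was called, and the list of mating type alpha genes had 1 gene measured and was not tested.

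**Figure D1:**
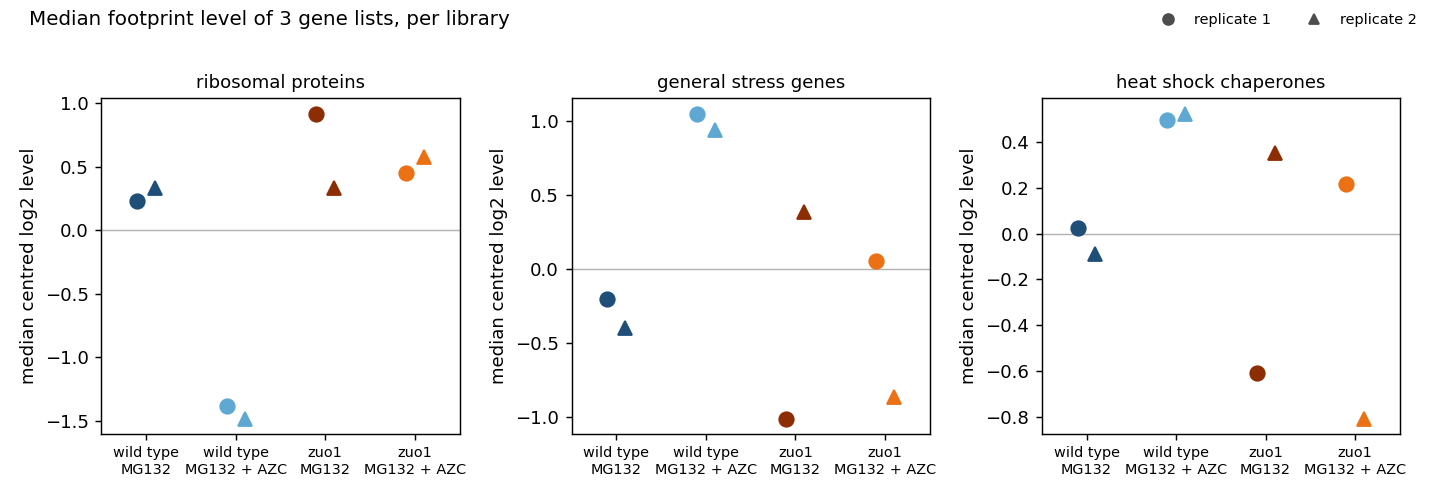
Median log2 level of 3 gene lists in each of the 8 libraries, relative to the mean over the libraries, with 1 point per library and the groups as labelled. The ribosomal protein median lay at -1.38 and -1.48 in the wild-type AZC libraries and between 0.335 and 0.917 in the 4 zuo1 libraries, while general stress and heat shock genes differed between zuo1 libraries of the same label.

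Ribosomes of wild type stood more often on proline codons when AZC was present. Relative occupancy of proline codons at the A site was 1.27 ± 0.010 with MG132 and 1.83 ± 0.0091 with MG132 plus AZC (mean ± SD, n = 2), a log2 change of 0.53 ± 0.127. The changes at the P and E sites were 0.30 and 0.20. Over all 8 libraries limma gave adjusted p = 0.11, 0.17 and 0.28 at the A, P and E sites, at the A site 0.016 without either zuo1 MG132 library, and with only the wild-type libraries in the fit it gave 8.6e-09, 3e-07 and 8.6e-06. Over all 8 libraries limma called 0 of the 61 codons at the 3 sites, with 35 features at an unadjusted p under 0.05 and no other tool run, against 16 risen and 48 fallen with only the wild-type libraries. For these occupancies, the fit of only the wild-type libraries was chosen after the data were seen. Among amino acids, tryptophan at the A site fell, by 0.229 (SE 0.033, adjusted p = 0.0089), from a relative occupancy of 1.62 ± 0.027 to 1.38 ± 0.044. The share of footprints off the middle P-site nucleotide went from 55.6% to 62.7% between the same groups. Whether this difference in codon resolution lowered tryptophan occupancy was not tested. Without wild-type MG132 replicate 1 or 2 or wild-type AZC replicate 2, limma called 0 amino acids, and 3 without any 1 of the zuo1 libraries. Footprint density 0 to 9 codons downstream of proline was 0.155 and 0.162 in the MG132 libraries and 0.34 and 0.315 in the AZC libraries, a change of 0.169 (adjusted p = 0.22). Farther downstream, density rose by 0.019 at 70 to 79 codons (adjusted p = 0.039) and 0.014 at 80 to 89 codons (adjusted p = 0.042), a pair of calls that became 0 when each of the wild-type or zuo1 MG132 libraries was left out and when alanine density was subtracted from proline density. Downstream of alanine codons the rises were 0.008 and 0.014 in these bins (limma, adjusted p = 0.077 and 0.017). At codons 2 to 15 the change was 0.074 (adjusted p = 0.33), and limma called 0 of 12 position bins, with 4 at an unadjusted p under 0.05, against 6 called without either zuo1 MG132 library.

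**Figure D2:**
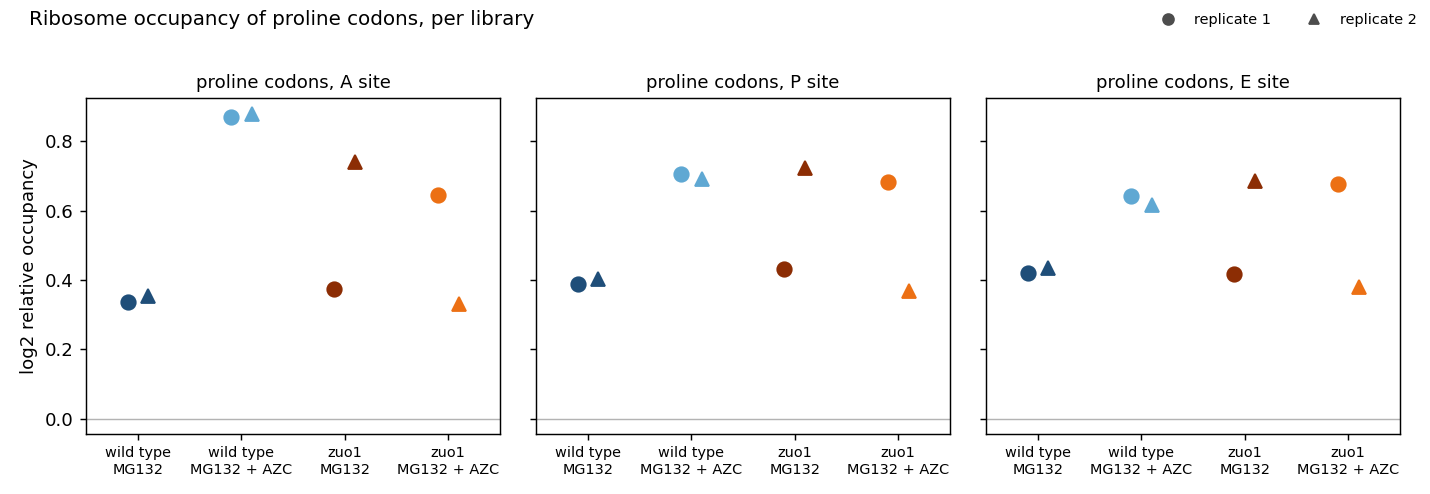
Relative occupancy of proline codons (log2, 0 is the mean of the gene) in each of the 8 libraries, with 1 point per library and the groups as labelled. At the A site the wild-type libraries lay at 0.337 and 0.353 with MG132 and at 0.87 and 0.88 with MG132 plus AZC, and the zuo1 libraries at 0.374 and 0.741 with MG132 and at 0.645 and 0.33 with MG132 plus AZC.

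The comparison of AZC with MG132 alone within zuo1 asked the same question in cells without Zuo1. Genes of ribosomal proteins, whose footprints fell in wild type, had a median log2 change of -0.10 in zuo1, with 0 of 138 called. SSB1 was at 1175 ± 497 CPM with MG132 and 1151 ± 154 with MG132 plus AZC (log2 0.04 ± 0.28, adjusted p = 1), SSB2 changed by 0.06 and SSZ1 by -0.07. HSP12 was at 2900 ± 2540 and 2009 ± 852, and SSA4 at 331 and 4024 in the 2 zuo1 MG132 libraries and at 2954 and 366 in the 2 zuo1 AZC libraries, so the replicates differed more than the groups. Limma called 0 genes, with 364 at an unadjusted p under 0.05, and limma-trend called 0, with 287. Counts were simulated for AZC in zuo1, with the median spread of the zuo1 groups in zuo1 and that of the wild-type groups in wild type. There 44.8% of 1.5-fold, 82.1% of 2-fold and 100% of 4-fold changes were called (30, 55 and 66 genes), as were 32 of 5095 unchanged genes. The unchanged genes were a larger share of the calls than the threshold of 0.05 aims at. Genes with a wider spread than the median, such as SSA4, are called less often than that.

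Without the zuo1 libraries numbered 2, AZC in zuo1 gave 562 risen and 462 fallen genes of 5321. In that setting SSA4 rose by 3.16, HSP26 rose by 2.98, HSP12 rose by 1.24 and SSB1 fell by 0.55. Each zuo1 group then held 1 library, which was taken to vary like the wild-type libraries. Replicates of zuo1 differed more, by a median of 0.327 and 0.203 against 0.143 and 0.17 in wild type. The setting, chosen after the data were seen, keeps the zuo1 pair that followed the wild-type response (slope 0.488). The pair left out ran against it (slope -0.388), so a response like that of wild type here is no separate evidence. In the same setting 27 of 30 general stress genes rose (28 adjusted over the list alone, median 1.19), 20 of 27 heat shock chaperones rose (21 adjusted over the list alone, median 0.72) and 84 of 138 ribosomal protein genes fell (115 adjusted over the list alone, median -0.47). Without the library labelled zuo1 MG132 replicate 2 alone, 84 genes were called.

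With all libraries, camera called 4 lists for AZC in zuo1, each without a called member over all genes or adjusted over the list alone. The medians were -0.10 for ribosomal proteins (adjusted p = 2.6e-06), -0.11 for proteasome subunits, -0.11 for oxidative phosphorylation and -0.17 for heat shock chaperones (adjusted p = 0.04). With an estimated correlation the adjusted p was 0.81, 0.81, 0.72 and 0.87, and fry called 0 lists. The heat shock median turned positive without the library labelled zuo1 MG132 replicate 2 (0.27) or without zuo1 MG132 plus AZC replicate 2 (0.33), and the ribosomal protein median without zuo1 MG132 replicate 1 (0.14), and heat shock was not called without either wild-type MG132 library (-0.25). The number of lists was 11 and 10 without the first or second zuo1 MG132 library and 8 without either zuo1 AZC library. Proline occupancy at the A site changed by -0.069 (adjusted p = 0.98), from 1.48 ± 0.27 to 1.41 ± 0.22, by -0.253 to 0.114 with 1 library left out and by 0.272 without the zuo1 libraries numbered 2. The codon CTT at the P site rose by 0.398 (adjusted p = 0.0095) and methionine at the A site by 0.217 (adjusted p = 0.014). Both calls rested on codon 31 of YLR154C-G, an open reading frame inside the ribosomal DNA, which held 4937 and 5471 footprints in the zuo1 AZC libraries, 2 and 113 in the zuo1 MG132 libraries and 1, 1722, 16 and 0 in the wild-type libraries. Without that gene the CTT change was -0.018 and the methionine change 0.028. Limma called 3 codons without either wild-type MG132 library or without zuo1 AZC replicate 1, 4 without zuo1 MG132 replicate 2 and 0 without zuo1 AZC replicate 2, and methionine was not called without either zuo1 MG132 library.

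Whether the AZC effect differed between the genotypes was tested as an interaction, where a positive value is a smaller fall or larger rise in zuo1. The fall of the ribosomal protein genes was smaller in zuo1, with 96 of 138 ribosomal protein genes past the threshold upwards and 0 downwards (132 and 1 adjusted over the list alone), at a median of 1.59. No gene was called in the interaction with the replicate number as a block (0 genes) or without any 1 of the 4 wild-type libraries or of the 2 zuo1 AZC libraries. The ribosomal protein genes with the largest differences were RPL21B (2.48), RPS22A (2.36), RPS0A (2.34), RPS9B (2.33 ± 0.23, adjusted p = 0.015) and RPL22A (2.30). SSB1 differed by 2.52 ± 0.39 (adjusted p = 0.022), SSB2 by 2.05 ± 0.33 (adjusted p = 0.023), ASC1 by 2.12, YEF3 by 2.32, TEF1 by 2.05 and the amino acid enzyme ILV5 by 2.60. PBI2, an inhibitor of a vacuolar protease, was the 1 gene past the threshold downwards (-1.21 ± 0.25, adjusted p = 0.048). It went from 99.4 ± 6.82 to 178 ± 19.0 in wild type and from 144 ± 32.4 to 109 ± 8.11 in zuo1.

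In the interaction, limma called 160 genes upwards and 1 downwards, with 1003 at an unadjusted p under 0.05. Camera called 10 lists, the ribosomal proteins with adjusted p = 6.1e-61. The adjusted p with an estimated correlation lay between 0.58 and 0.72 for these lists, 0.58 for the ribosomal proteins among them. None passed in that test. Besides the ribosomal proteins, the counts over all genes and, in brackets, adjusted over the list alone were 4 (20) of 65 for ribosome biogenesis with NOP58 at 2.26 and NOP7 at 1.44, 4 (14) of 17 for elongation factors, 3 (16) of 26 for initiation factors with TIF1 at 1.28, 2 (14) of 45 for Gcn4-type genes with LEU9 at 1.63, and 5 (12) of 24 for glycolysis with PDC1 at 1.57. They were 2 (5) of 15 for the chaperonin with CCT7 at 1.09 and 2 (5) of 9 for ribosome-associated chaperones. Members of the 2 called lists with negative medians were 0 of 27 heat shock chaperones (median -0.79) and 1 of 30 general stress genes (median -1.27, the member YGP1 at 0.79), with the same counts adjusted over the list alone. By fry, the ribosomal proteins moved up on balance (adjusted p = 0.042). HSP12 had a difference of -2.83 ± 0.82 (adjusted p = 0.11).

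Without the zuo1 libraries numbered 2, the interaction gave 399 genes upwards and 31 downwards, 125 of 138 ribosomal protein genes (median 1.26) among the former, and the heat shock median was 0.30. The gene count was 1228 and 298 without the first or second zuo1 MG132 library and 82 with median-of-ratios scaling. Proline occupancy at the A site had an interaction of -0.599 ± 0.179 (adjusted p = 0.22). It was -0.783 without zuo1 MG132 replicate 1 and -0.258 without the zuo1 libraries numbered 2, both fits that leave 1 library in a zuo1 group. The 2 called codons were CTT at the P site (0.559) and ATG at the A site (0.34), and the called amino acid was methionine at the A site. The codon count was 1 without wild-type MG132 replicate 1 or without either zuo1 MG132 library and 0 without any 1 of the other 3 wild-type libraries, and methionine was not called without wild-type MG132 replicate 2 or wild-type AZC replicate 2. Without YLR154C-G, limma called 0 codons, the CTT difference was 0.069 and that of methionine 0.127 (adjusted p = 0.18).

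The comparison of zuo1 with wild type under MG132 alone asked what loss of Zuo1 changed before AZC was added. More genes of ribosome biogenesis and of oxidative phosphorylation rose than fell in zuo1, and more genes of glycolysis and of the unfolded protein response fell than rose. LTV1 (YKL143W), a factor of small-subunit assembly, was at 15.04 ± 1.89 CPM in wild type and 81.8 ± 37.5 in zuo1 (log2 2.44 ± 0.42, adjusted p = 0.011). TOD6 (YBL054W), a repressor of ribosome biogenesis genes, was at 5.02 ± 1.88 and 33.0 ± 11.4 (log2 2.81 ± 0.48, adjusted p = 0.011). PHO84 (YML123C, chromosome XIII, 24037 to 25800), the high-affinity phosphate transporter, was at 46.5 ± 9.95 and 1.66 ± 0.858 (log2 -4.92 ± 0.47, adjusted p = 0.0012). ADH1 (YOL086C), the main alcohol dehydrogenase of fermentation, was at 17390 ± 1130 and 5369 ± 908 (log2 -1.71 ± 0.16, adjusted p = 0.001). ZUO1 had a log2 change of -7.03, and SSB1 (-0.11), SSB2 (-0.20) and SSZ1 (-0.40) did not pass the threshold.

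Under MG132, limma called 331 genes as higher and 443 as lower in zuo1. The largest rises besides TOD6 and LTV1 were DIA1 (3.36), MNC1 (2.81), the a-factor gene MFA1 (2.26), NQM1 (2.18), MIN10 (2.13) and NCA3 (2.07). The largest falls besides ZUO1 and PHO84 were ADE17, an enzyme of purine synthesis (-4.09), the quinone reductase ZTA1 (-3.02), the cell wall mannoproteins TIR1 (-2.93) and TIR3 (-2.92), the arginine-degrading enzyme CAR2 (-2.60) and HIS4 of histidine synthesis (-2.50). RTA1 of the drug resistance list rose by 4.86, from 0.562 ± 0.323 to 19.0 ± 5.79 CPM, and the count of genes was 43 and 65 without the first or second wild-type MG132 library, 339 and 334 without the first or second wild-type AZC library and 1496 without the library labelled zuo1 MG132 replicate 2. It was 69 with only these 2 groups in the fit, 487 with the replicate number as a block and 2001 without the zuo1 libraries numbered 2.

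Camera called 6 lists for zuo1 under MG132, none of which passed with an estimated correlation. With an estimated correlation the adjusted p was 0.7 for ribosome biogenesis, 0.83 for ribosomal proteins, 0.42 for oxidative phosphorylation, 0.37 for glycolysis, 0.7 for Gcn4-type genes and 0.37 for the unfolded protein response. Of 65 ribosome biogenesis genes, 29 rose and 0 fell (52 and 0 adjusted over the list alone, median 1.22), with UTP18 at 1.79 and UTP20 at 1.36, both of the small-subunit processome. Of 138 ribosomal protein genes, 23 rose and 2 fell (30 and 2 adjusted over the list alone, median 0.35), with RPS29A at 1.23 and, in the other direction, RPS11B at -1.55. Of 35 oxidative phosphorylation genes, 15 rose and 1 fell (19 and 1 adjusted over the list alone, median 0.48), with ATP15 of the ATP synthase at 1.12, the NADH dehydrogenase NDE1 at 1.16 and COX8 at 0.97. Of 24 glycolysis genes, 1 rose and 17 fell (1 and 19 adjusted over the list alone, median -1.05), with ENO1 at -1.48, PGK1 at -1.23 and HXK2 at -1.14. Of 45 Gcn4-type genes, 2 rose and 12 fell (3 and 19 adjusted over the list alone, median -0.36), with LEU1 at -1.70, BAT1 at -1.06 and CPA1, of arginine synthesis, at 1.83. Of 22 genes of the unfolded protein response, 0 rose and 6 fell (1 and 8 adjusted over the list alone, median -0.42), with the disulfide isomerases EUG1 at -1.04 and PDI1 at -0.69 and the chaperone LHS1 at -0.82. The number of lists called was 12 and 11 without the first or second zuo1 MG132 library. Among the lists not called, the mitochondrial chaperone HSP60 fell (-1.06), as did the cell wall genes CWP1 (-1.69) and CHS3, a chitin synthase (-1.38), the iron-related mannoproteins FIT2 and FIT3 (-2.01 each), arginase CAR1 (-1.73) and the ubiquitin ligase UFD2 (-0.60), while the transporter FLR1 (1.26), GRE2 (1.04), the histone gene HHT1 (0.71) and the proteasome genes SEM1 (0.58) and PRE3 (0.54) rose.

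Ribosomes of zuo1 under MG132 were denser at the start of coding sequences. Density at codons 2 to 15, relative to the gene mean over 1329 genes, was 1.29 ± 0.00024 in wild type and 1.77 ± 0.11 in zuo1, a log2 change of 0.454 ± 0.058 (adjusted p = 0.0027), and no other position bin was called, against 4 bins called without the zuo1 libraries numbered 2. Tryptophan at the A site fell by 0.282 (SE 0.033, adjusted p = 0.0021), from 1.62 ± 0.027 to 1.33 ± 0.032, which with its 1 codon TGG made the 1 codon and 1 amino acid called. The share of footprints off the middle P-site nucleotide was 55.6% in wild type and 63.7% in zuo1. Its part in the tryptophan change was not tested. The codon count was 0 without any 1 wild-type library or the library labelled zuo1 MG132 replicate 2, 28 without zuo1 MG132 replicate 1 and 4 without either zuo1 AZC library, and the amino acid count was 12 without zuo1 MG132 replicate 1 and 2 without either zuo1 AZC library. Proline at the A site changed by 0.212 (adjusted p = 0.43), and by 0.029 to 0.396 with 1 library left out, the latter past the threshold (adjusted p = 0.043, without zuo1 MG132 replicate 1). Downstream of proline, density fell by 0.018 at 70 to 79 codons and fell by 0.017 at 80 to 89 codons (adjusted p = 0.031 each). Those 2 calls became 0 without any 1 of the wild-type or zuo1 MG132 libraries and when alanine density was subtracted, and 5 without either zuo1 AZC library. Downstream of alanine codons the changes in these bins were -0.014 and -0.015 (limma, adjusted p = 0.015 each).

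**Figure D3:**
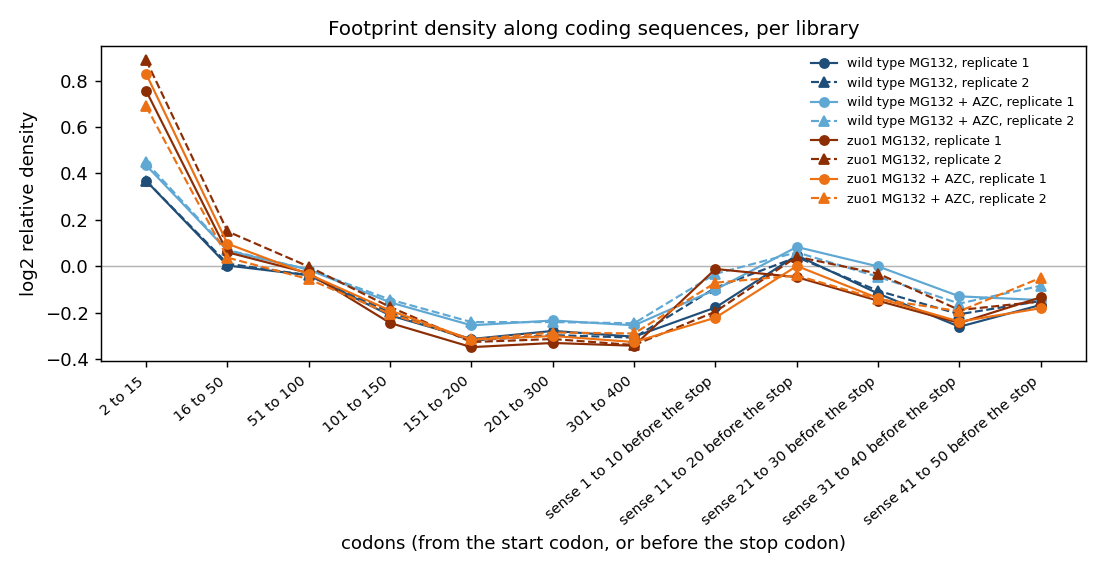
Footprint density (log2, relative to the gene mean) in 12 position bins along the coding sequences of 1329 genes, with 1 line per library. At codons 2 to 15 the 4 zuo1 libraries lay at 0.756, 0.888, 0.829 and 0.689 and the 4 wild-type libraries between 0.368 and 0.448.

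The comparison of zuo1 with wild type under MG132 plus AZC asked how the genotypes differed in the presence of the analogue. Most ribosome biogenesis and ribosomal protein genes were higher in zuo1, and 13 of 30 general stress genes were lower. NSR1 (YGR159C), which acts in rRNA processing, was at 18.6 ± 2.29 CPM in wild type and 415 ± 134 in zuo1 (log2 4.44 ± 0.66, adjusted p = 0.0029). SSB1 was at 218 ± 39.6 and 1151 ± 154 (log2 2.41 ± 0.27, adjusted p = 0.00089), SSB2 rose by 1.85 and SSZ1 by 0.63 (adjusted p = 0.049). HSP104, the disaggregase, fell by 2.14 (adjusted p = 0.047), and SSA3, an inducible Hsp70, fell by 2.69 (adjusted p = 0.016). The largest rises besides NSR1 were UTP25 (4.33), NOG1 (4.05), TOD6 (4.03), SYO1 (3.99), CGR1 (3.96), LTV1 (3.93) and SSF1 (3.84), all but the repressor TOD6 factors of ribosome assembly or of ribosomal protein import. The largest falls besides ZUO1 (-6.35) were PHO84 (-3.02), ZTA1 (-3.01), EMI2 (-2.72), YBR053C (-2.70), MRX18 (-2.66) and glycogen synthase GSY1 (-2.64).

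Limma called 996 genes as higher and 543 as lower in zuo1 under MG132 plus AZC. The number was 567 and 358 without the first or second wild-type AZC library, 577 without the library labelled zuo1 MG132 plus AZC replicate 2 and 1901 without both zuo1 libraries numbered 2. Camera called 11 lists, none of which passed with an estimated correlation. The adjusted p with an estimated correlation was 0.48 for 9 of them, 0.64 for the heat shock chaperones and 0.51 for glycolysis. Of 138 ribosomal protein genes, 134 rose and 1 fell (135 and 1 adjusted over the list alone, median 1.94), with RPL42A at 3.19 and RPS29A at 3.14. Of 65 ribosome biogenesis genes, 63 rose (65 adjusted over the list alone, median 2.88), with UTP18 at 3.66 and NOP56 at 2.59. Of 17 elongation factors, 11 rose (13 rose and 1 fell adjusted over the list alone, median 1.04), with YEF3 at 2.62, and of 26 initiation factors, 17 rose and 1 fell (21 and 1 adjusted over the list alone, median 0.68), with PAB1 at 1.39. Of 35 oxidative phosphorylation genes, 17 rose and 1 fell (22 and 2 adjusted over the list alone, median 0.50), with ATP20 at 1.41, and of 15 chaperonin genes, 7 rose (8 adjusted over the list alone, median 0.47), with CCT7 at 1.01. Of 30 general stress genes, 0 rose and 13 fell (0 and 18 adjusted over the list alone, median -1.31), with UGP1 at -2.04 and glucokinase GLK1 at -1.68. Of 27 heat shock chaperones, 1 rose and 4 fell (2 and 11 adjusted over the list alone, median -0.76), with SGT2 at 0.48 and UBI4, polyubiquitin, at -0.76. Of 9 mitochondrial chaperones, 2 fell (3 adjusted over the list alone, median -0.51), HSP60 at -0.79 and MGE1 at -0.51. Of 22 genes of the unfolded protein response, 6 fell (6 adjusted over the list alone, median -0.15), with SIL1 at -1.22 and EUG1 at -0.88. Of 24 glycolysis genes, 4 rose and 5 fell (4 and 6 adjusted over the list alone, median -0.22), with the glucose transporters HXT1 at 2.44 and HXT7 at -2.26.

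Of 9 ribosome-associated chaperones, 6 rose under MG132 plus AZC and 1, ZUO1, fell, a list camera did not call. Relative density at codons 2 to 15 was 1.36 ± 0.0085 in wild type and 1.69 ± 0.12 in zuo1, a log2 change of 0.318 ± 0.058 (adjusted p = 0.018). The change was 0.311 and 0.324 without the first or second wild-type AZC library and 0.248 without zuo1 MG132 plus AZC replicate 1, each no longer past the threshold. Density in the bin that ends at codon 200 fell by 0.069 (adjusted p = 0.029), a call lost without any 1 wild-type library or zuo1 AZC replicate 1, and 7 bins were called without either zuo1 MG132 library and 9 without the zuo1 libraries numbered 2. Proline at the A site changed by -0.387 (adjusted p = 0.28, and 0.048 without either zuo1 MG132 library), by -0.544 to -0.229 with 1 library left out and by -0.229 without the zuo1 libraries numbered 2. Its codons CCC and CCG passed the threshold on their own with -0.513 and -0.661 (adjusted p = 0.049 each). The arginine codons CGG at the A site (-0.818) and CGA at the P site (-0.391) fell, while CGC at the P site (0.317), TTC at the A site (0.146), CTT at the P site (0.403) and ATG at the A site (0.183) rose, which made 8 codons, and methionine at the A site rose as the 1 amino acid called (adjusted p = 0.041). Without any 1 wild-type library limma called 0 amino acids, 4 without either zuo1 MG132 library and 2 without zuo1 AZC replicate 2. Without YLR154C-G limma called 0 of them, CTT changed by -0.031 and ATG by -0.011, and the count was 0 without either wild-type AZC library or zuo1 MG132 plus AZC replicate 2, 2 without either wild-type MG132 library, 17 without either zuo1 MG132 library and 5 without zuo1 MG132 plus AZC replicate 1. Of 13 distance bins from proline, 4 were called, from 0.020 at 20 to 11 codons upstream to -0.028 at 70 to 79 codons downstream. That number was 2 without either wild-type or either zuo1 MG132 library or without wild-type AZC replicate 2, and 0 when alanine density was subtracted. Downstream of alanine codons the changes were -0.017 at 70 to 79 codons and -0.027 at 80 to 89 codons (limma, adjusted p = 0.0059 and 0.0017). In the 2 zuo1 AZC libraries the middle P-site nucleotide held 34.09% and 34.28% of footprints, nearly an even share. This limits the codon values of this comparison.

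**Figure D4:**
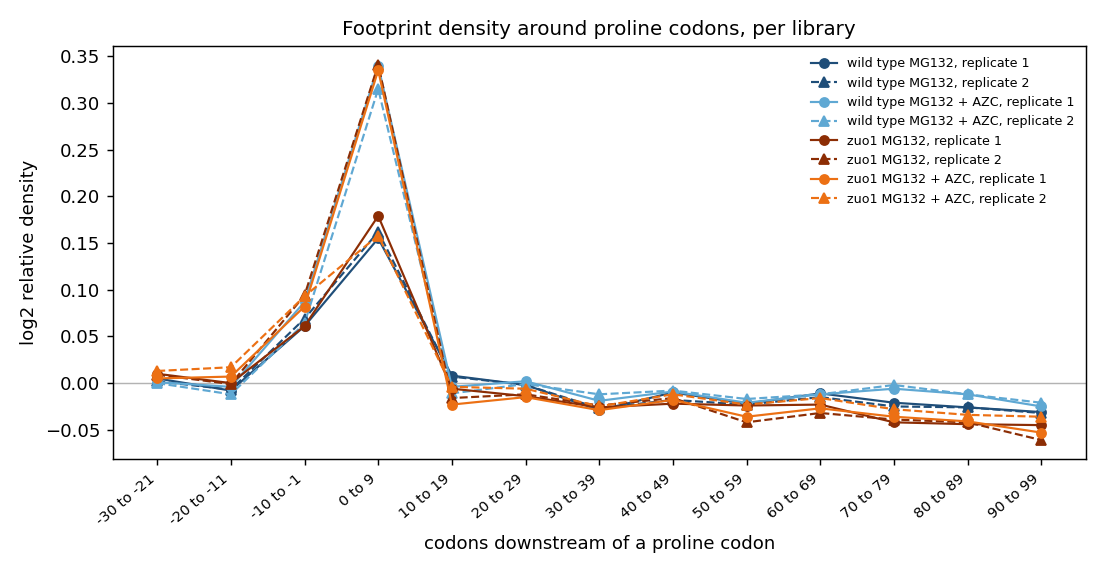
Footprint density around proline codons in bins of 10 codons (log2, relative to the gene mean, 2347 genes), with 1 line per library. The bin of 0 to 9 codons lay at 0.155 and 0.162 in the wild-type MG132 libraries, at 0.34 and 0.315 in the wild-type AZC libraries, at 0.179 and 0.341 in the zuo1 MG132 libraries and at 0.335 and 0.158 in the zuo1 AZC libraries.

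The zuo1 effect averaged over both treatments sets all zuo1 against all wild-type libraries whatever their treatment, and was added for that reason. Its errors and calls still depend on the treatment labels, and with the libraries fitted as 2 groups limma called 1307 genes and 0 codons. All 65 ribosome biogenesis genes rose in zuo1 (65 adjusted over the list alone, median 2.05), and 131 of 138 ribosomal protein genes rose and 1 fell (133 and 2 adjusted over the list alone, median 1.15). TOD6 rose by 3.42 ± 0.41 (adjusted p = 0.00078), LTV1 by 3.19, SYO1 by 3.18, UTP25 by 3.10, NSR1 by 2.97, CGR1 and NOG2 by 2.91 each and NOG1 by 2.84. SSB1 rose by 1.15 ± 0.19 (adjusted p = 0.0032) and SSB2 by 0.83 (adjusted p = 0.0065), and SSZ1 changed by 0.12 (adjusted p = 0.55). Neither SSB1 nor SSB2 passed the threshold under MG132 alone, so their averaged rise rests on the AZC libraries, where wild type had fallen. The centred ribosomal protein median was -1.38 and -1.48 in the wild-type AZC libraries. It was 0.231 and 0.331 in wild type with MG132 and 0.335 to 0.917 in zuo1, so most of that averaged rise lay under AZC too. PHO84 fell by 3.97 ± 0.33 (adjusted p = 0.0002), followed by ADE17 (-3.27), ZTA1 (-3.01), TIR3 (-2.67), TIR1 (-2.66), MRX18 (-2.48) and YBR053C (-2.37).

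Averaged over both treatments, limma called 1166 genes as higher and 868 as lower, 1263 genes in all without wild-type MG132 replicate 1 and 1208 without wild-type AZC replicate 2. Camera called 10 lists, none of which passed with an estimated correlation. With an estimated correlation the adjusted p was 0.29 for the unfolded protein response, 0.49 for ribosomal proteins, ribosome biogenesis, glycolysis, oxidative phosphorylation and mitochondrial chaperones, and 0.75 for initiation factors, chaperonin, general stress and heat shock. Besides the ribosomal lists, 24 of 35 oxidative phosphorylation genes rose and 2 fell (26 and 3 adjusted over the list alone, median 0.48), 15 of 26 initiation factors rose and 1 fell (16 and 1 adjusted over the list alone, median 0.38) and 8 of 15 chaperonin and prefoldin genes rose (8 adjusted over the list alone, median 0.28). In the other direction, 2 of 24 glycolysis genes rose and 16 fell (2 and 17 adjusted over the list alone, median -0.63), 12 of 22 genes of the unfolded protein response fell and 1 rose (13 and 1 adjusted over the list alone, median -0.39), and 11 of 30 general stress genes fell (11 adjusted over the list alone, median -0.65). Of 9 mitochondrial chaperones, 3 fell (3 adjusted over the list alone, median -0.48), HSP60 at -0.92 and SSC1, the matrix Hsp70, at -0.56 among them. Of 27 heat shock chaperones, 1 rose and 4 fell (0 adjusted over the list alone, median -0.30), SSA1 at -0.65 among them. Of 15 drug resistance genes, 7 rose and 3 fell, a list not called by camera (adjusted p = 0.074) and moving up on balance by fry (adjusted p = 0.0025), with RTA1 at 4.54 and GRE2 at 1.14. The ribosome-associated chaperones had a median of 0.16 and a mean of -0.27, the mean taking in the lost ZUO1, and were not called.

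Density at codons 2 to 15 was higher in each zuo1 library than in each wild-type library, by 0.386 ± 0.041 on average (adjusted p = 0.00097), and density fell by 0.045, fell by 0.045 and fell by 0.047 in the 3 bins between codons 150 and 400 (adjusted p = 0.029 each). Those 3 calls were lost without any 1 wild-type library or zuo1 AZC replicate 1, and 7 bins were called without zuo1 MG132 replicate 2. Of the 61 codons at the 3 sites, 3 features rose and 10 fell. The largest falls were the arginine codons CGG at the A site (-0.625 ± 0.116, adjusted p = 0.034) and CGA at the P site (-0.385 ± 0.054, adjusted p = 0.021) and A site (-0.38 ± 0.078, adjusted p = 0.047). CGC at the P site (0.245), CGT at the A site (0.185) and GTA at the A site (0.107) rose, and tryptophan at the A site fell by 0.181 (adjusted p = 0.0043), the 1 amino acid called, with 7 called without zuo1 MG132 replicate 1 and 3 without zuo1 AZC replicate 2. Relative occupancy of tryptophan was 1.62 in wild type with MG132, against 1.38 in wild type with AZC and 1.33 and 1.31 in zuo1. The wild-type MG132 group also had the lowest share of footprints off the middle P-site nucleotide. In every zuo1 library but MG132 replicate 1 footprints were spread nearly evenly over the nucleotides of the codon, which limits these codon comparisons. The codon number was 0 without wild-type MG132 replicate 1 or either wild-type AZC library, 1 without wild-type MG132 replicate 2, 38 without zuo1 MG132 replicate 1, 3 and 7 without the first or second zuo1 AZC library and 20 without YLR154C-G. Of 13 distance bins, 6 were called, the largest -0.023 at 70 to 79 codons (adjusted p = 0.0017), with 2 or 3 called without any 1 of the wild-type or zuo1 MG132 libraries and 0 when alanine density was subtracted. Downstream of alanine codons density changed by -0.015, -0.021 and -0.023 at 70 to 79, 80 to 89 and 90 to 99 codons. Limma gave adjusted p = 0.0015, 0.00093 and 0.00085 for these, so the falls far downstream were not particular to proline.

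Single values per library were compared by exact two-sided permutation tests, in which 0.0286 is the smallest p for 4 libraries against 4. They take the 8 libraries as independent, although the protocol describes 2 aliquots of a culture, treated with and without AZC, and 4 cultures would allow only 3 splits. More zuo1 footprints had the start codon in the P site, 1.63% ± 0.28 with MG132 and 1.15% ± 0.033 with MG132 plus AZC against 0.961% ± 0.099 and 0.708% ± 0.044 in wild type (difference 0.555 points, exact p = 0.0286, adjusted p = 0.086). Codons 2 to 5 held 4.24% ± 0.32 and 4.02% ± 0.33 of zuo1 footprints against 2.39% ± 0.026 and 2.51% ± 0.096 (difference 1.68 points, exact p = 0.0286, adjusted p = 0.086). Stop codons in the P site differed by 0.0595 points and mean polarity, where a negative value is a shift to the 5' end, by -0.0242 (exact p = 0.0286 and adjusted p = 0.086 for each). Over codons after the first 15 and before the last 5 the polarity difference was -0.00625 (exact p = 0.114, adjusted p = 0.229). There the libraries of the genotypes overlapped. Stop codons in the A site differed by -0.0013 points between the genotypes (exact p = 1). The share of footprints with the P-site nucleotide off the middle position was 55.6% ± 0.29 and 62.7% ± 0.66 in wild type and 63.7% ± 1.9 and 65.8% ± 0.14 in zuo1, a genotype difference of 5.56 points (exact p = 0.0571, adjusted p = 0.147), or 4.31 to 6.9 points with 1 library left out. The first, middle and last nucleotide held 33.30%, 34.09% and 32.61% in zuo1 MG132 plus AZC replicate 1. They held 33.96%, 34.28% and 31.76% in its replicate 2 and 33.85%, 34.98% and 31.17% in zuo1 MG132 replicate 2. These nearly even shares show little reading frame, which limits codon comparisons between the genotypes. With AZC, counts rose with coding length (slope difference 0.0953) and fell with mean expression (slope difference -0.0668, or -0.0857 to -0.0518 with 1 library left out), each with exact p = 0.0286 and adjusted p = 0.086. The slope on a gene's proline content differed by 0.0494 between treatments (exact p = 0.143, adjusted p = 0.286) and by 0.0794 within wild type, where 0.33 is the smallest p that 2 libraries against 2 allow.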

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

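The explanations weighed in this part, and the tests set against them, were chosen after the result they bear on had been seen. Planned beforehand were the interaction itself and, as general alternatives, the replicate block and the libraries left out in turn. So were the estimated correlation, median-of-ratios scaling and equal gene weights.

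The difference between the genotypes in their response to AZC was tested as an interaction, and each result named here passed that test. The test called 161 genes, 10 gene lists, 2 codon occupancies and 1 amino acid occupancy. None of the 10 lists passed with an estimated correlation (adjusted p between 0.58 and 0.72). The gene count was 0 with the replicate number as a block and 0 without any 1 of the 4 wild-type or 2 zuo1 AZC libraries. It was 1228 and 298 without the first or second zuo1 MG132 library. The median differences (zuo1 minus wild type) were 1.59 for ribosomal proteins, 1.69 for ribosome biogenesis, 0.97 for elongation and termination factors, 0.65 for initiation factors, 0.60 for Gcn4-type genes, 0.80 for glycolysis, 0.72 for ribosome-associated chaperones, 0.37 for the chaperonin, -0.79 for heat shock chaperones and -1.27 for general stress genes. Without the zuo1 libraries numbered 2, the median was 0.30 for heat shock chaperones and -0.06 for general stress genes. The codon and amino acid calls rested on codon 31 of YLR154C-G, without which 0 codons and 0 amino acids were called by limma, with 10 and 6 at an unadjusted p under 0.05.

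The first pattern is that the zuo1 libraries numbered 2 lie with the other treatment, since over 2215 genes called with only the wild-type libraries the AZC minus MG132 difference of each pair had slopes on the wild-type response of 0.968 and 1.02 for the wild-type pairs (the genes were chosen in those), 0.488 for the zuo1 pair numbered 1 and -0.388 for the zuo1 pair numbered 2. The labels of these 2 libraries may have been exchanged, since both lie out of place, each with the other treatment. Against this, the share of footprints with the start codon in the P site was 1.83% and 1.43% with MG132 and 1.12% and 1.17% with MG132 plus AZC in zuo1 (0.892%, 1.03%, 0.677% and 0.739% in wild type), and the slope on coding length was -0.109 and -0.0425 against 0.0184 and 0.05 in zuo1, which follows the labels. Other single values paired the zuo1 libraries as an exchange would. Codons 2 to 5 held 4.01% and 4.47% with MG132 and 4.26% and 3.79% with MG132 plus AZC. The slope on proline content was -0.0614 and 0.00262 against 0.00061 and -0.0205. Wild-type AZC footprints mixed into the library labelled zuo1 MG132 replicate 2 are argued against, as its ZUO1 footprints allow at most 5.17% where its AZC-responsive genes need a median of 59.8% (lower quartile 39.9%, 108 genes), and so is codon resolution, as the 2 zuo1 AZC libraries differ by 0.315 in proline occupancy with 0.19 points between their shares on the middle nucleotide. An exchange, cultures that differed in their exposure and other differences between the cultures stay open, and the groups were kept as labelled.

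The second pattern is that ribosomal protein genes fell with AZC in wild type and less so in zuo1. The exchange above does not account for it, since the medians of the 4 zuo1 libraries, whatever their labels, span 0.582 where wild type changed by -1.71 with replicates at most 0.1 apart. With median-of-ratios scaling the median difference was 1.51 against 1.59, which argues against the scaling. A weaker exposure of zuo1 cells to AZC stays open, since proline occupancy at the A site was 0.271 higher with AZC in the zuo1 pair numbered 1 against 0.533 and 0.527 in the wild-type pairs. The interaction was -0.258 without the libraries numbered 2, a value that rests on 1 zuo1 library per treatment. Labelled replicates of zuo1 lay at 0.374 and 0.741 with MG132 and at 0.645 and 0.33 with AZC, farther apart than that. The change in that zuo1 pair was 0.253 at the P site (wild-type pairs 0.317 and 0.29), but 0.26 at the E site (0.22 and 0.181) and 0.156 in density 0 to 9 codons after proline (0.185 and 0.153, with a span of 0.183 over the zuo1 libraries) go the other way, so an effect of Zuo1 on the response cannot be told apart from a weaker exposure.

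The third pattern is more footprints at codons 2 to 15 in zuo1. Codon resolution is argued against, since the library labelled zuo1 MG132 replicate 1 lies 0.33 above the higher wild-type AZC library in relative density (1.69 against 1.36) with at most 0.84 points between their shares on the middle nucleotide. Depth is argued against, since the lowest zuo1 library lies 0.25 above the highest wild-type library in relative density (1.61 against 1.36), and a few abundant genes are, since with equal gene weights the change was 0.259 ± 0.0211 (adjusted p = 0.000239). What makes the zuo1 libraries differ there, and how the ribosomes were arrested in each culture, was not tested.

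Each split of the 8 libraries into 4 and 4 was fitted as 2 groups, 35 splits in all. For genes, 1 split, the genotype itself, gave as many as its 1307 calls, the highest other giving 103. For density by distance from proline 1 split gave as many as its 7, the highest other giving 1. That result is not particular to proline, since density 80 to 89 codons downstream of alanine was lower in zuo1 too (-0.021 averaged over both treatments). Chance cannot be excluded for gene lists (16 splits gave as many as the 9 of the genotype, the highest other 12). At least 1 gene list was called by camera at the preset correlation in 33 of the 35 splits. For density along coding sequences 2 splits gave as many as the 1 bin of the genotype (highest other 1), and chance cannot be excluded for the number of bins. The smallest adjusted p over the bins (limma) was 3.08e-06 for the genotype, at codons 2 to 15. Among the other splits the smallest was 0.0412, near the stop codon. Thus 1 of 35 splits, the genotype itself, gave as small a value. The results for genes, for distance from proline and for codons 2 to 15 are beyond chance only if the 8 libraries are independent. Per the protocol 2 aliquots of a culture were treated with and without AZC, and 4 cultures make 3 splits, too few for a share under 0.05. For codons and amino acids the genotype split called 0, so that all 35 splits gave as many in either case (highest other 17 and 11). The count of splits decides nothing there. The split with 103 genes, 17 codons and 11 amino acids sets the wild-type MG132 libraries with zuo1 MG132 replicate 1 and zuo1 AZC replicate 2, which is the structure of the first pattern.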

How the results depend on the processing

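The settings chosen after the data were seen were limma-trend, the fits without the zuo1 libraries numbered 2, the block with crossed numbers in zuo1, the removal of YLR154C-G, the zuo1 average and, for features other than genes, the fits of the compared groups alone. Among the values of results under alternatives, 743 kept their direction and side of the threshold or lay within 1.5 times, 182 moved, 28 newly passed the threshold, 3 no longer passed and 5 turned. For named genes these were 4432 kept, 809 no longer past, 69 newly past and 2 turned, for named lists 540 kept, 98 no longer past and 5 turned, and for named codons and amino acids 251 kept, 214 no longer past and 14 turned. A value past the threshold in neither setting counts as kept whatever its sign. A repeat with DESeq2, planned beforehand, was not run, as count models were kept for tables deposited as counts. Where no reason is given, the cause was not tested.

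With only the groups compared, the spread of the other groups no longer enters the test. This gave 2215 genes for AZC in wild type and 69 for zuo1 in MG132, codon counts of 64, 3, 0 and 5 for AZC in wild type, AZC in zuo1, zuo1 in MG132 and zuo1 in MG132 plus AZC, and 5 and 0 distance bins for AZC in wild type and zuo1 in MG132 plus AZC. Proline changes newly past the threshold were 0.530, 0.303 and 0.201 at the A, P and E sites for AZC in wild type and -0.387 at the A site for zuo1 in MG132 plus AZC, and density changes newly past it were 0.062 at codons 16 to 50 and 0.074 at codons 2 to 15 for AZC in wild type. With a replicate block, gene counts were 104 for AZC in wild type, 0 for the interaction and 487 for zuo1 in MG132, codon counts were 4 for AZC in zuo1, 0 for the interaction, 0 for zuo1 in MG132 and 1 for zuo1 in MG132 plus AZC, and distance bins were 0 for AZC in wild type, 0 for zuo1 in MG132, 2 for zuo1 in MG132 plus AZC and 2 for the average. With the block crossed in zuo1, the interaction gave 1039 genes, 16 codons and 1 distance bin, and AZC in zuo1 gave 8 codons. Median-of-ratios scaling gave 82 genes for the interaction. With an estimated correlation 0 gene lists were called in any of the 6 comparisons, a setting that widens the variance of each list, and fry called 0 for AZC in zuo1 and 3 for the interaction.

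Without the zuo1 libraries numbered 2, where each lone zuo1 library is assumed to vary like the wild-type libraries, gene counts were 2172 for AZC in wild type, 1024 for AZC in zuo1, 430 for the interaction and 2001 for zuo1 in MG132, with 13 lists for AZC in zuo1 and 11 for zuo1 in MG132. Codon counts were 64, 69, 6, 10, 55 and 51 in the order AZC in wild type, AZC in zuo1, interaction, zuo1 in MG132, zuo1 in MG132 plus AZC and average, and distance bins were 5 for AZC in wild type, 1 for AZC in zuo1, 4 for zuo1 in MG132 and 9 for zuo1 in MG132 plus AZC. Turned values were proline for AZC in zuo1 (0.272, 0.252 and 0.259 at the A, P and E sites), proline at the E site (0.049) and codons 16 to 50 (0.029) for zuo1 in MG132 plus AZC, the heat shock list for AZC in zuo1 (0.72) and the interaction (0.30), and SSB1 (-0.55) and SSB2 (-0.45) for AZC in zuo1. Newly past the threshold were proline at the A site for AZC in wild type (0.530), the interaction (-0.258), zuo1 in MG132 plus AZC (-0.229) and the average (-0.10), proline at the P (0.303) and E sites (0.201) for AZC in wild type, codons 16 to 50 for AZC in wild type (0.062), zuo1 in MG132 (0.053) and the average (0.041), and codons 2 to 15 for AZC in wild type (0.074).

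Without YLR154C-G, codon counts were 2 for AZC in wild type, 0 for AZC in zuo1, 0 for the interaction, 0 for zuo1 in MG132 plus AZC and 20 for the average, and CTT at the P site turned for AZC in zuo1 (-0.018) and zuo1 in MG132 plus AZC (-0.031), as did ATG and methionine at the A site for the latter (-0.011 each). With the first 50 codons left out, which removes the position of that gene, codon counts were 0 for AZC in zuo1, 0 for the interaction and 0 for zuo1 in MG132 plus AZC, with CTT at -0.020 and -0.060, ATG and methionine at -0.010 each and CGC at the P site at -0.005. With 500 or more footprints per gene, which leaves fewer genes, they were 0, 0 and 3, with 2 for zuo1 in MG132 and 8 for the average, 3 distance bins for the average, CTT at -0.063 and -0.101 and ATG and methionine at -0.032 each. With equal gene weights they were 0, 0 and 0, with 5 for zuo1 in MG132, CGC at -0.004, and 0 distance bins for AZC in wild type, 0 for zuo1 in MG132 plus AZC and 2 for the average. Equal weights also took codons 2 to 15 (-0.123) and 16 to 50 (-0.081) past the threshold for AZC in zuo1, and codons 16 to 50 for zuo1 in MG132 (0.071) and the average (0.061). Capped positions gave 24 codons for the average. Proline minus alanine density gave 0 distance bins for AZC in wild type, 0 for zuo1 in MG132, 0 for zuo1 in MG132 plus AZC and 0 for the average.

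Leaving out each library in turn gave ranges of 81 to 1733, 0 to 84, 0 to 1228, 43 to 1496, 358 to 2177 and 1208 to 2507 genes in the order above, 4 to 11 lists for AZC in zuo1 and 6 to 12 for zuo1 in MG132. Codons ranged over 0 to 4 for AZC in zuo1, 0 to 2 for the interaction, 0 to 28 for zuo1 in MG132, 0 to 17 for zuo1 in MG132 plus AZC and 0 to 38 for the average, and distance bins over 0 to 2 for AZC in wild type, 0 to 5 for zuo1 in MG132, 2 to 6 for zuo1 in MG132 plus AZC and 2 to 7 for the average. Proline at the A site ranged over 0.521 to 0.538 for AZC in wild type, -0.783 to -0.416 for the interaction, 0.029 to 0.396 for zuo1 in MG132 and -0.544 to -0.229 for zuo1 in MG132 plus AZC. Density at codons 16 to 50 ranged over 0.053 to 0.143 for zuo1 in MG132 and 0.026 to 0.071 for the average, and at codons 2 to 15 over 0.248 to 0.388 for zuo1 in MG132 plus AZC. The AZC difference ranged over -0.505 to -0.192 points for start codons, -0.379 to 0.336 for codons 2 to 5, 3.2 to 6.4 for the P-site nucleotide off the middle and -0.0857 to -0.0518 for the slope on expression, and the zuo1 difference over 4.31 to 6.9 points for the P-site nucleotide and -0.0568 to -0.0184 for the slope on expression. List medians that turned for AZC in zuo1 were heat shock, 0.27 without zuo1 MG132 replicate 2 and 0.33 without zuo1 AZC replicate 2 (range -0.66 to 0.33), and ribosomal proteins, 0.14 without zuo1 MG132 replicate 1 (range -0.39 to 0.14). At the depth and spread of these libraries, of which the smallest held 1986105 footprints, 47.8% of 1.5-fold changes simulated for AZC in wild type were called.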

Other observations

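All the tests in this part were chosen after the data were seen, and the genes named were chosen after their values were seen.

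Among the phosphate genes looked at first, which also held PHO89, PHO8 and SPL2, PHO84, PHO5 and VTC3 had lower values in zuo1 under both treatments. PHO84, the phosphate transporter, was at 46.5 ± 9.95 and 20.7 ± 0.725 CPM in wild type without and with AZC and at 1.66 ± 0.858 and 2.42 ± 0.229 in zuo1. The acid phosphatase PHO5 was at 27.3 ± 4.18 and 14.7 ± 1.2 against 3.53 ± 1.42 and 5.14 ± 0.485, and VTC3, of polyphosphate synthesis, at 213 ± 27.5 and 149 ± 27.2 against 41.3 ± 4.32 and 47.6 ± 0.589. The hypothesis that the phosphate regulon is lower as a set was tested on 6 members not looked at before, VTC1, VTC2, VTC4, PHO81, PHO12 and PHO86. Their median change was -0.65, 5 fell and 0 rose, and the median lay at percentile 0.18 of 10000 random sets matched on expression. The whole set of 12, which includes the genes behind the hypothesis, had a median of -0.85, with 10 fallen and 0 risen. All were measured in the same 8 libraries. Members of the set may move together with the genes behind the hypothesis, which random sets do not take into account. The percentile is therefore no independent test. Lower footprint counts of the phosphate regulon in zuo1 may be part of the strain difference, whether through Zuo1 or through another variant of the strain.

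A like hypothesis for purine and one-carbon genes came from ADE17, at 316.5 ± 150 and 124 ± 69.6 CPM in wild type and 18.4 ± 4.05 and 20.3 ± 0.957 in zuo1. The 6 members not looked at before, ADE6, ADE16, MTD1, GCV1, GCV2 and GCV3, had a median of 0.19, at percentile 82.9, with 3 risen and 0 fallen, 4 of the 6 being one-carbon genes. The whole set of 14, with the members looked at first, had a median of -0.26, at percentile 3.8, with 3 risen and 6 fallen, so whether the set is lower stays open.

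The genes beside ZUO1 on chromosome VII had lower values in zuo1: BIO2 at 88.9 ± 0.894 and 55.8 ± 3.75 in wild type and 32.1 ± 5.1 and 27.4 ± 0.408 in zuo1, ERV29 at 464 ± 15 and 356 ± 34.4 and 256 ± 4.77 and 219.9 ± 28.5. AGA1, of mating agglutination, had 130, 143, 113 and 381 CPM in the wild-type and 352, 117, 108 and 431 in the zuo1 libraries, in the order of the labels.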
